A study of Mus musculus with 6 samples.

How the data were processed

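RNA from whole lungs of Balb/c mice was sequenced 7 days after intravenous injection of 250000 cells of 4T1, a mouse mammary carcinoma line of Balb/c origin that colonises the lung. The injected cells were either unmodified (WT, 3 libraries) or lacked PD-L1 (KO, 3 libraries), and the lungs had been perfused with 20 mL of PBS, per the labels' protocols. The host mice are not labelled as edited, so KO refers to the injected tumour cells throughout.

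The deposited values were whole-number read counts per Ensembl gene, which the authors obtained by aligning paired-end reads to mm10 (GRCm38) with STAR 2.5 and counting with HTSeq 0.6.1, per the labels' protocols and the submitters' processing notes. The annotation release, the strand setting, the counting mode and any read filter are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and near-identical genes (the H2 class I genes, the Tgtp, Ifit and Gbp families, immunoglobulin and T cell receptor segments) may share or lose reads. Balb/c sequence also differs from the reference genome, most of all in the H2 region, which affects both groups alike. Each library was a separate table with 35275 gene rows, and 0 rows named no gene. Symbols, exonic lengths and coordinates (GRCm38, counted from 1) came from GENCODE M21 by exact Ensembl identifier. A symbol was found for 34490 identifiers, and the 785 others held at most 0.094% of the counts of a library. Rows for 15196 reference genes with identifiers numbered above the last one in the tables, among them Gbp5, Gbp6, Ighd and Cd244, were not analysed here, nor were 5850 other reference genes without a row. The tables held counts for 21769 genes.

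Total counts were 14711459, 16932114 and 15355747 in WT replicates 1 to 3 and 15410121, 15222408 and 16469780 in KO replicates 1 to 3. A count of 0 therefore allows, at 3 counts, up to 0.177 to 0.204 CPM (the usual counts scaled by library size, as computed by edgeR) in a library. Such floors cover counting error only. No 2 libraries held identical values. Their counts differed by 15.36 to 57.92 times the variance expected from sampling (chi-square per degree of freedom), so each was used as 1 replicate. The labels speak of mice and number the lungs 1 to 3 per group, without stating that each library came from 1 animal, so p-values measure the spread between these samples.

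Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test (TMM normalisation, filterByExpr with a minimum count of 10, estimateDisp, glmQLFit with robust=TRUE, design of group alone), as KO minus WT. The p-values were adjusted by Benjamini-Hochberg over 15191 genes, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken as the size of the fold change divided by the square root of F. Group values are mean CPM ± SD over 3 libraries, with TMM-scaled library sizes. Lists of genes were tested with limma 3.58.1 camera (preset correlation 0.01, 3 measured genes at least), which asks whether a list ranks above or below the other genes. The tests were two-sided. Of 42 lists, 41 had enough measured members. The sex-linked list had 1 and was not tested. List values per library are means of log2(CPM + 1).

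Groups, tests, lists, the rule for named genes and all alternatives except the length and GC offset were chosen before the data were examined. The rule named the genes the series title points to, then in each direction the 10 genes with the largest log2 fold change among those that passed the test at a mean log2 CPM of 1 or more with all KO libraries on the same side of all WT libraries, excluding Gm, Rik and pseudogene symbols. It also named the 3 members with the smallest p in each called list and in the interferon, cytotoxic, T cell, chemokine, checkpoint and MHC class I lists, and at most 1 member of other lists.

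The alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, robust=FALSE, leaving out each replicate, the replicate number as a block, thresholds of 0.01 and 0.1, a minimum fold of 1.5 (glmTreat), and for the lists an estimated correlation, fry and camera on voom values. The labels do not pair the samples across groups, and equal replicate numbers were not treated as pairs. An offset per library from a smooth fit on exonic length and GC content (splines with 5 degrees of freedom) was added after the data had been seen, as were a list of pan-leukocyte genes and 4 gene families defined by symbol. The procedure was tested on simulated counts for the same 15191 genes and 6 libraries, with 200 genes changed in each of 5 simulations. It recovered 27.6% of genes changed 1.5-fold, 70.4% of those changed 2-fold and 91.2% of those changed 3-fold, and 7.5% of its calls were false. The changed genes were drawn only from those with a log2 mean CPM above 1, so the shares recovered do not cover lower genes. The simulated genes varied independently of each other and without a length trend, unlike the real genes. These shares therefore need not hold for the calls in the real libraries.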

Results

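Lungs of mice injected with WT 4T1 cells (3 libraries) and with PD-L1 KO 4T1 cells (3 libraries) were compared 7 days after injection. The title of the series points to tumour PD-L1, myeloid PD-1, type I interferon and the recruitment of cytotoxic T cells. The comparison therefore asks how the RNA of the lung differs when the injected tumour cells lack PD-L1. Loss of PD-L1 cannot be told apart here from any other difference between the injected WT and KO cells, or from a difference in tumour load. Libraries held 14711459 to 16932114 counts, with 17520 to 19156 genes detected. Each library is RNA of the whole organ, in which host cells, infiltrating leukocytes and tumour cells are mixed.

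In lungs with KO tumour cells, 28 of 40 type I interferon-stimulated genes, 14 of 21 MHC class I and 8 of 12 MHC class II antigen presentation genes and several monocyte, chemokine and immunoglobulin genes rose, and 2 of 11 platelet genes fell. These are counts of single genes, and no list fixed in advance was called as a whole when the correlation of its members was taken from the data (lowest adjusted p = 0.114 with an estimated correlation). The counts also depended on single libraries: with 1 library left out, 6 to 31 of the 40 type I interferon-stimulated genes rose. Bst2, an antiviral membrane protein induced by interferon, rose from 61.5 ± 11.1 to 150.2 ± 18.7 CPM (SD, n = 3 per group). Ly6c2, a marker of inflammatory monocytes, rose from 14.1 ± 3.18 to 43.7 ± 10.2 CPM, and Ccl2, which attracts monocytes, from 12.8 ± 1.93 to 35.6 ± 7.60 CPM. Of the 20 genes in the list of monocytes and interstitial macrophages, 4 rose and 16 did not pass over all genes. In the opposite direction, the platelet chemokine gene Ppbp fell from 17.9 ± 3.82 to 2.57 ± 0.752 CPM. Among genes of T cells and cytotoxic effector cells, no single member of the 2 lists passed the test over all genes, and Cd8a was at 6.35 ± 1.49 CPM in WT and 12.3 ± 1.59 CPM in KO lungs.

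The targeted gene was examined first. Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095), had 910, 912 and 1132 counts in the WT libraries and 1514, 3013 and 4929 counts in the KO libraries. This is 63.5 ± 10.4 CPM in WT lungs and 198.5 ± 101.5 CPM in KO lungs, a log2 difference of 1.65 ± 0.42 (SE) that did not pass the test (edgeR adjusted p = 0.161), although all 3 KO libraries lay above all 3 WT libraries. Host cells keep the gene and reads from an edited allele can still be counted, so Cd274 checks the labels of these lungs only in part.

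Among the other genes the title points to, Cxcl10, a chemokine for activated T cells encoded on chromosome 5 (92346638 to 92348889), rose from 7.56 ± 1.98 to 45.9 ± 24.2 CPM, with a log2 fold change of 2.61 ± 0.44 (edgeR adjusted p = 0.0416). The call for Cxcl10 was lost without WT replicate 1, 2 or 3 or KO replicate 2, at adjusted p of 0.193, 0.157, 0.112 and 0.167. Its neighbour Cxcl9 (92321347 to 92328079), which binds the same receptor, had 8.35 ± 4.79 CPM in WT and 83.5 ± 59.0 CPM in KO lungs. The log2 difference of 3.33 ± 0.75 did not pass (edgeR adjusted p = 0.133), and the KO libraries ranged from 30.38 to 147.0 CPM. Both Cd274 and Cxcl9 passed without KO replicate 1, at adjusted p of 1.86e-05 and 0.0319. For Cd8a, a subunit of the CD8 co-receptor of cytotoxic T cells, the log2 difference was 0.95 ± 0.26 (adjusted p = 0.0881). For Pdcd1, which encodes PD-1, the log2 difference was 0.80 ± 0.27 (adjusted p = 0.173), and for the granule protease gene Gzmb it was 0.49 ± 0.24 (adjusted p = 0.359). The interferon receptor gene Ifnar1 had 155.8 ± 17.2 and 160.0 ± 11.7 CPM, a log2 difference of 0.04 ± 0.11. No read was counted for Ifnb1 in any of the 6 libraries, so interferon beta RNA was not detectable at this depth, and its floor lay at 0.177 to 0.204 CPM per library. Of the interferon alpha genes in the list, Ifna5 had 8 counts in KO replicate 3 and 0 in the other libraries, and the others had 0.

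**Figure D1:**
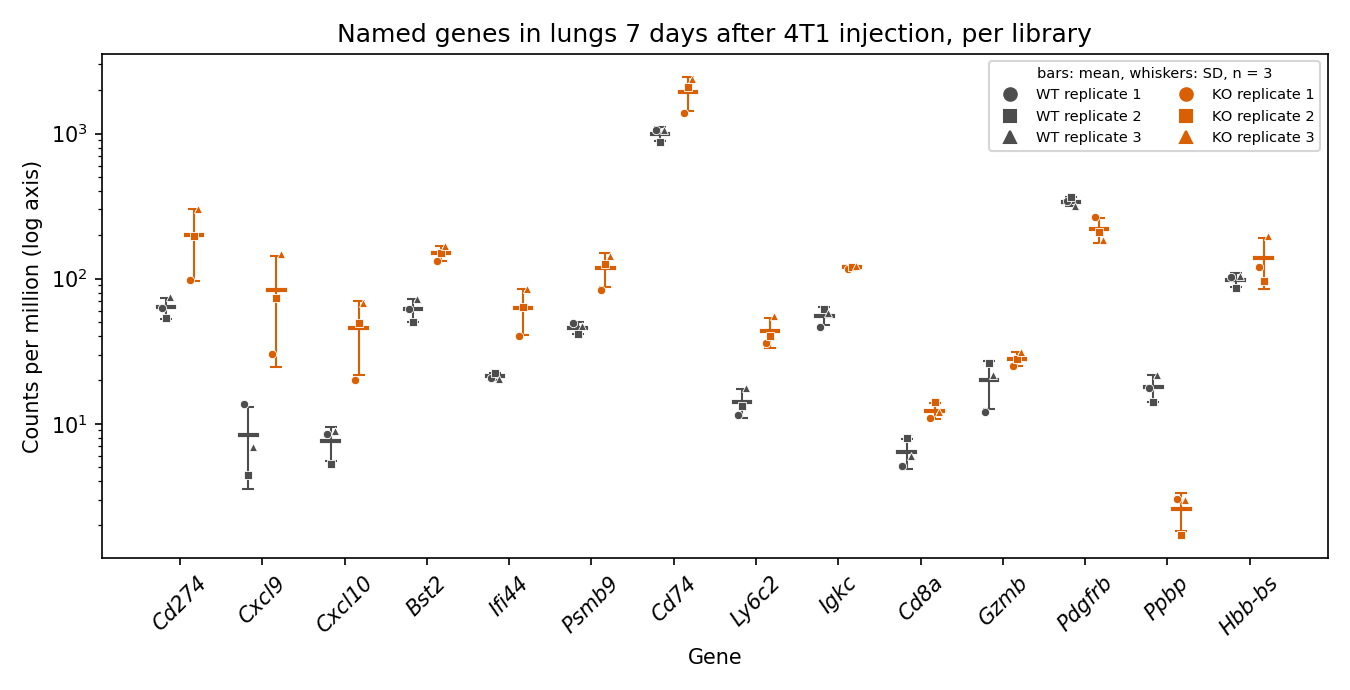
CPM (log axis) of 14 named genes in each of the 6 libraries, with WT lungs in grey and KO lungs in orange; horizontal bars are means and whiskers SD (n = 3). All KO points lie above all WT points for Cd274, Cxcl9, Cxcl10, Bst2, Ifi44, Psmb9, Cd74, Ly6c2, Igkc and Cd8a, and below them for Pdgfrb and Ppbp.

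Over all genes, 170 of 15191 were higher and 51 were lower in KO lungs (edgeR quasi-likelihood test). At an unadjusted p under 0.05 there were 2221 genes. In all 221 called genes the 3 KO libraries lay on one side of the 3 WT libraries. The test selects such genes, so this is no separate support for the calls. Of all tested genes 19.7% were separated in this way, where chance gives 10%, but genes do not vary independently. The median log2 fold change was 1.02 among the higher genes, 92 of which changed more than 2-fold, and −0.56 among the lower genes, 2 of which did. Of the 170 higher genes, 78 belonged to the lists fixed in advance and 61 to the 4 interferon and MHC lists, while 6 of the 51 lower genes were in any list.

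The largest increases by the fixed rule were those of Calhm6, Cxcl11, Slamf8, Ighv2-9, Ly6i, Cxcl10, Tgtp1, Dnase1l3, Zbp1 and Ifi27l2a. Calhm6, a channel gene expressed by myeloid cells, rose from 0.685 ± 0.476 to 9.69 ± 5.11 CPM (log2 fold change 3.79 ± 0.58, adjusted p = 0.00891). Cxcl11 rose from 1.35 ± 0.845 to 14.1 ± 11.6 CPM, with an adjusted p of 0.0487, and the reference lists it as a polymorphic pseudogene. Zbp1, a cytosolic nucleic acid sensor, rose from 14.2 ± 1.91 to 66.2 ± 30.4 CPM (adjusted p = 0.0144). The remaining 6 genes other than Cxcl10 had log2 fold changes from 2.20 (Ifi27l2a) to 3.24 (Slamf8). The largest decreases were those of Ppbp, Nrgn, Fat3, Lrat, Amot, Synpo2, Ppp2r3a, Ltbp2, Mtss1l and Clstn2. Ppbp (chromosome 5, 90768518 to 90770063) fell by 2.79 ± 0.29 and Nrgn by 1.90 ± 0.28 on the log2 scale. Lrat, a retinol-esterifying enzyme, fell by 0.79 ± 0.13, from 240.0 ± 40.8 to 139.0 ± 16.3 CPM. Ltbp2, an extracellular matrix protein, fell by 0.69 ± 0.11, and the remaining 6 genes had log2 fold changes between −0.65 (Clstn2) and −0.81 (Fat3).

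The type I interferon-stimulated list held 40 measured genes, of which 28 rose over all genes tested, 39 rose when adjusted over the list alone, and none fell by either count. Its median log2 fold change was 1.14, with an interquartile range of 0.65 to 1.47, and all 40 members were on the higher side. The list ranked above the other genes (limma camera adjusted p = 7.64e-63), but not with its members' correlation taken from the data (adjusted p = 0.114 with an estimated correlation). Besides Bst2, Stat2, which carries the type I interferon signal to the nucleus, rose by a log2 fold change of 0.95 ± 0.13 and Ifi44 by 1.57 ± 0.21 (edgeR adjusted p = 0.00482 for both). Of 23 measured interferon-gamma-induced genes, 11 rose over all genes and 23 rose adjusted over the list alone, with a median of 1.54 (camera adjusted p = 1.19e-49, and adjusted p = 0.114 with an estimated correlation). Irf1, a transcription factor of the interferon response, rose from 269.7 ± 47.1 to 507.9 ± 55.7 CPM, Tgtp1 from 6.93 ± 0.374 to 36.8 ± 18.9 CPM, and Nlrc5, the activator of MHC class I genes, from 42.4 ± 2.39 to 93.2 ± 29.3 CPM. Leaving out WT replicates 1, 2 and 3 and KO replicates 1, 2 and 3 in turn, 1, 1, 6, 23, 0 and 5 of the interferon-gamma-induced genes rose. Of the type I interferon-stimulated genes, 6, 6, 18, 31, 8 and 10 rose in the same order. The 3 measured genes of the list of interferons and their receptors did not pass, with a median of 0.12. Ifnar2 among them had a log2 difference of 0.27 ± 0.14. In the list of nucleic acid sensing and interferon induction, 1 of 15 genes rose over all genes and 5 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.000329, and adjusted p = 0.117 with an estimated correlation). The gene that rose was Unc93b1, which traffics endosomal Toll-like receptors (log2 fold change 0.58 ± 0.11). Irf5 (0.66 ± 0.16, adjusted p = 0.0571) and Tmem173 (0.76 ± 0.23, adjusted p = 0.126), which encodes STING, did not pass. With the same libraries left out, 0, 0, 1, 5, 0 and 0 sensing genes rose. Their median was 0.38 without WT replicate 2.

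In the MHC class I list 14 of 21 genes rose over all genes and 19 adjusted over the list alone, with a median log2 fold change of 0.83 (camera adjusted p = 5.04e-38, and adjusted p = 0.114 with an estimated correlation). Tap2, a subunit of the peptide transporter, rose from 54.0 ± 0.927 to 109.0 ± 16.5 CPM, the immunoproteasome subunit gene Psmb9 from 46.0 ± 4.28 to 118.2 ± 31.1 CPM, and H2-T23 from 295.4 ± 41.4 to 690.9 ± 159.1 CPM. The other 7 did not pass. In the MHC class II list 8 of 12 genes rose over all genes and 10 adjusted over the list alone, with a median of 0.97 (camera adjusted p = 2.1e-19, and adjusted p = 0.114 with an estimated correlation). The invariant chain gene Cd74 rose from 1001 ± 105.6 to 1948 ± 511.7 CPM, H2-Aa from 36.6 ± 5.55 to 77.6 ± 22.9 CPM, and Ifi30 by a log2 fold change of 0.74 ± 0.12. Without WT replicates 1, 2 and 3 and KO replicates 1, 2 and 3 in turn, 6, 5, 10, 18, 5 and 7 class I genes and 1, 0, 6, 10, 0 and 1 class II genes rose.

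Myeloid lists also ranked higher. In RNA of the whole lung, more cells of a kind and more RNA of these genes per cell cannot be told apart. Of 20 genes of monocytes and interstitial macrophages, 4 rose over all genes, and 10 rose and 1 fell adjusted over the list alone, with a median of 0.46 (camera adjusted p = 2.01e-11, and adjusted p = 0.114 with an estimated correlation). The Fc receptor genes Fcgr1 (log2 fold change 1.82 ± 0.31) and Fcgr4 (1.55 ± 0.32) rose with Ly6c2 (1.64 ± 0.21), and 1 monocyte gene rose without WT replicate 1 or 2 or KO replicate 2 or 3, 4 without WT replicate 3 (median 0.72) and 7 without KO replicate 1. Among 18 neutrophil genes, S100a8 (1.13 ± 0.19) and S100a9 (1.10 ± 0.19) rose, 3 rose adjusted over the list alone, and Wfdc21 did not pass (1.22 ± 0.38, adjusted p = 0.14). The neutrophil median was 0.52 (camera adjusted p = 2.88e-06, and adjusted p = 0.311 with an estimated correlation). With 1 library left out in turn (WT replicates 1, 2 and 3, then KO replicates 1, 2 and 3), 0, 0, 3, 2, 0 and 0 neutrophil genes, 1, 1, 1, 4, 1 and 1 dendritic cell genes and 0, 0, 4, 5, 0 and 0 cytokine genes rose. The neutrophil median was 0.28 without WT replicate 1, and the dendritic cell median 0.60 without WT replicate 3. In the dendritic cell list 2 of 17 genes rose, Bst2 and Ccr9, and 3 adjusted over the list alone, with a median of 0.37 (adjusted p = 5.66e-05, and adjusted p = 0.297 with an estimated correlation). Bst2 is also an interferon-induced gene. Siglech, a marker of plasmacytoid dendritic cells, had a log2 difference of 1.15 ± 0.30 (adjusted p = 0.0784). None of 17 alveolar macrophage genes rose over all genes by edgeR, 15 of which had positive log2 differences, and 1 rose adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.00417, and adjusted p = 0.512 with an estimated correlation). Marco was at 1.99 ± 1.69 and 8.31 ± 0.140 CPM (adjusted p = 0.0962), and the log2 differences of Ctsk and Chil3 were 0.60 ± 0.29 and 0.47 ± 0.23. The alveolar macrophage call was lost without WT replicate 2 (median 0.16, adjusted p = 0.097) and KO replicate 2 (0.21, adjusted p = 0.0611). Its median was 0.43 without WT replicate 3. Of 24 cytokine and effector genes, S100a8 and S100a9 rose, and 7 rose adjusted over the list alone, with a median of 0.47 (adjusted p = 4.39e-06, and adjusted p = 0.157 with an estimated correlation). Both are listed as neutrophil genes too. Il1a had a log2 difference of 0.87 ± 0.23 (adjusted p = 0.0984).

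Of 33 measured chemokine genes, 4 rose and 1 fell over all genes, and 10 rose and 2 fell adjusted over the list alone, with a median of 0.49 (camera adjusted p = 3.82e-08, and adjusted p = 0.186 with an estimated correlation). Ccl2 (log2 fold change 1.47 ± 0.19), Ccl7 (2.03 ± 0.39), Cxcl10 and Cxcl11 rose, and Ppbp fell. With 1 library left out in turn (WT replicates 1, 2 and 3, then KO replicates 1, 2 and 3), 2, 1, 6, 7, 1 and 2 chemokine genes and 0, 1, 1, 3, 0 and 0 checkpoint genes rose, and Ppbp fell each time. The chemokine median was 0.85 without WT replicate 3. In the checkpoint and co-stimulation list 1 of 24 genes rose, Ctla4, and 2 rose adjusted over the list alone, with a median of 0.46 (adjusted p = 9.96e-07, and adjusted p = 0.21 with an estimated correlation). Ctla4 rose from 5.29 ± 1.71 to 18.0 ± 6.20 CPM, and Lgals9 had a log2 difference of 0.42 ± 0.11 (adjusted p = 0.088).

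None of 26 T cell genes passed over all genes by edgeR, 22 of which had positive log2 differences, and 2 rose adjusted over the list alone, with a median of 0.38 (camera adjusted p = 9.07e-05, and adjusted p = 0.518 with an estimated correlation). Cd3g (0.81 ± 0.21, adjusted p = 0.0805), Thy1 (0.69 ± 0.20, adjusted p = 0.1) and Lck (0.53 ± 0.19, adjusted p = 0.195) had the smallest p-values. The T cell median was 0.23 without WT replicate 1 (adjusted p = 0.0472) and 0.68 without WT replicate 2 (adjusted p = 3.19e-13). Of the T cell genes 2 rose without KO replicate 1. None of 21 cytotoxic effector genes passed over all genes, 17 of which had positive log2 differences, and 2 rose adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00353, and adjusted p = 0.548 with an estimated correlation). Besides Cd8a, Klrk1 had a log2 difference of 0.72 ± 0.21 (adjusted p = 0.122), and Ifng was at 0.273 ± 0.263 and 1.77 ± 1.34 CPM (adjusted p = 0.22). The call for the cytotoxic list was lost without WT replicate 1, where its median was 0.08 (adjusted p = 0.337). This median was 0.55 without WT replicate 2 and 0.38 without KO replicate 2. The NK cell list, with 9 genes and a median of 0.09, did not pass. In the regulatory T cell list 1 of 10 genes rose, Ctla4, and 4 adjusted over the list alone, with a median of 0.71 (adjusted p = 0.000285, and adjusted p = 0.114 with an estimated correlation). Foxp3 had a log2 difference of 1.29 ± 0.42 (adjusted p = 0.154) and Il2ra of 0.98 ± 0.31 (adjusted p = 0.141). Of 16 B cell genes, Cd72 (1.51 ± 0.27) and Cd37 (0.55 ± 0.13) rose and 10 rose adjusted over the list alone, with a median of 0.61 (adjusted p = 1.09e-09, and adjusted p = 0.186 with an estimated correlation). Ms4a1, which encodes CD20, did not pass (0.97 ± 0.23, adjusted p = 0.0572). With 1 library left out in turn (WT replicates 1, 2 and 3, then KO replicates 1, 2 and 3), 0, 0, 1, 1, 1 and 0 B cell genes, 0, 1, 1, 2, 0 and 0 regulatory T cell genes and 2, 3, 2, 2, 2 and 2 immunoglobulin genes rose. The immunoglobulin median was 1.03 without WT replicate 3. Of 12 plasma cell and immunoglobulin genes, Igkc rose from 55.7 ± 7.97 to 120.1 ± 3.07 CPM and Ighm from 80.1 ± 9.56 to 163.4 ± 32.9 CPM, and 3 rose adjusted over the list alone. That list had a median of 0.67 (adjusted p = 4.04e-06, and adjusted p = 0.114 with an estimated correlation), and Jchain a log2 difference of 1.14 ± 0.28 (adjusted p = 0.085). In the thymocyte list 1 of 7 genes rose, Ccr9, a homing receptor that the dendritic cell list also holds, and 2 adjusted over the list alone. Its median was 0.35 (adjusted p = 0.0368, and adjusted p = 0.516 with an estimated correlation), and Cd4 had a log2 difference of 0.51 ± 0.25. The thymocyte call was lost without WT replicate 1 (median 0.22, adjusted p = 0.215), WT replicate 3 (0.34, adjusted p = 0.0873) and KO replicate 2 (0.16, adjusted p = 0.359). The thymocyte median was 0.53 without WT replicate 2 or KO replicate 1. With 1 library left out, Ccr9 passed in 1 of the 6 fits, the one without KO replicate 1. None of 32 cell cycle genes passed over all genes by edgeR, 31 of which had positive log2 differences, and 10 rose adjusted over the list alone. The cell cycle median was 0.71 (camera adjusted p = 2.21e-11, and adjusted p = 0.278 with an estimated correlation), and Top2a, Cdk1 and Ccna2 had log2 differences of 1.04 ± 0.26, 1.42 ± 0.39 and 1.29 ± 0.36. Without KO replicate 1, 5 cell cycle genes rose, and without KO replicate 3 the median was 0.47.

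Platelet and stromal lists ranked lower in KO lungs. CPM is a share of whole-lung RNA, so a fall within stromal cells cannot be told apart from fewer stromal cells or more RNA from other cells. With the length and GC offset, 16 of the 51 genes called lower stayed called. Of 11 platelet and megakaryocyte genes, Ppbp and Nrgn fell over all genes and 6 fell adjusted over the list alone, with a median of −1.02 and all 11 on the lower side (camera adjusted p = 2.69e-12, and adjusted p = 0.114 with an estimated correlation). Itga2b, the integrin of the platelet fibrinogen receptor, was at 15.6 ± 1.09 and 7.97 ± 1.95 CPM (adjusted p = 0.0581). Without KO replicate 3, 1 platelet gene fell, and 3 fell without KO replicate 1. Of 26 fibroblast and matrix genes, Pdgfrb fell from 340.4 ± 23.1 to 220.7 ± 43.2 CPM and Pdgfra from 656.3 ± 57.5 to 477.7 ± 22.4 CPM, and Col6a3 did not pass (−0.45 ± 0.10, adjusted p = 0.0501). Adjusted over the list alone, 12 fell and 1 rose, with a median of −0.30 (adjusted p = 2.22e-07, and adjusted p = 0.114 with an estimated correlation). With 1 library left out in turn (WT replicates 1, 2 and 3, then KO replicates 1, 2 and 3), 0, 0, 1, 6, 0 and 0 fibroblast genes, 0, 0, 2, 1, 0 and 0 smooth muscle genes and 0, 0, 1, 2, 0 and 1 endothelial genes fell. Without KO replicate 1, 2 fibroblast genes rose. The smooth muscle median was −0.21 without WT replicate 2. Of 11 smooth muscle genes, Synpo2 fell (−0.74 ± 0.17) and 5 fell adjusted over the list alone, with a median of −0.39 (adjusted p = 2.41e-05, and adjusted p = 0.278 with an estimated correlation). Mylk and Myh11 had log2 differences of −0.44 ± 0.10 and −0.73 ± 0.22. Of 20 endothelial genes, Vwf, the von Willebrand factor gene, fell from 917.3 ± 80.1 to 606.1 ± 60.0 CPM by both counts, the one over all genes and the one adjusted over the list alone. The endothelial median was −0.14 (adjusted p = 0.0128, and adjusted p = 0.649 with an estimated correlation), and Emcn and Tie1 had log2 differences of −0.42 ± 0.13 and −0.29 ± 0.12. The endothelial call was lost without WT replicate 1 (median −0.03, adjusted p = 0.337), KO replicate 2 (−0.10, adjusted p = 0.131) and KO replicate 3 (−0.11, adjusted p = 0.1). The endothelial median was −0.22 without WT replicate 2 or KO replicate 1. None of 13 alveolar type 1 genes passed over all genes or adjusted over the list alone, 2 of which had positive log2 differences, with a median of −0.17 (camera adjusted p = 0.0148, and adjusted p = 0.649 with an estimated correlation). Cldn18, Akap5 and Rtkn2 had log2 differences of −0.38 ± 0.12, −0.32 ± 0.14 and −0.26 ± 0.12. That call was lost without WT replicate 1 (median −0.14, adjusted p = 0.0606), WT replicate 2 (−0.09, adjusted p = 0.243), KO replicate 2 (−0.13, adjusted p = 0.0733) and KO replicate 3 (−0.12, adjusted p = 0.136). The type 1 median was −0.26 without WT replicate 3 and −0.28 without KO replicate 1. None of 18 circadian clock genes passed over all genes and 1 fell adjusted over the list alone, with a median of −0.14 (adjusted p = 0.0273, and adjusted p = 0.512 with an estimated correlation). The log2 differences of Clock, Cry1 and Tef were −0.44 ± 0.10, −0.56 ± 0.20 and −0.36 ± 0.15. The circadian call was lost without WT replicate 2 (median −0.13, adjusted p = 0.104) and KO replicate 3 (0.05, adjusted p = 0.302). Circadian medians were −0.27, −0.32 and −0.28 without WT replicate 1, KO replicate 1 and KO replicate 2.

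**Figure D2:**
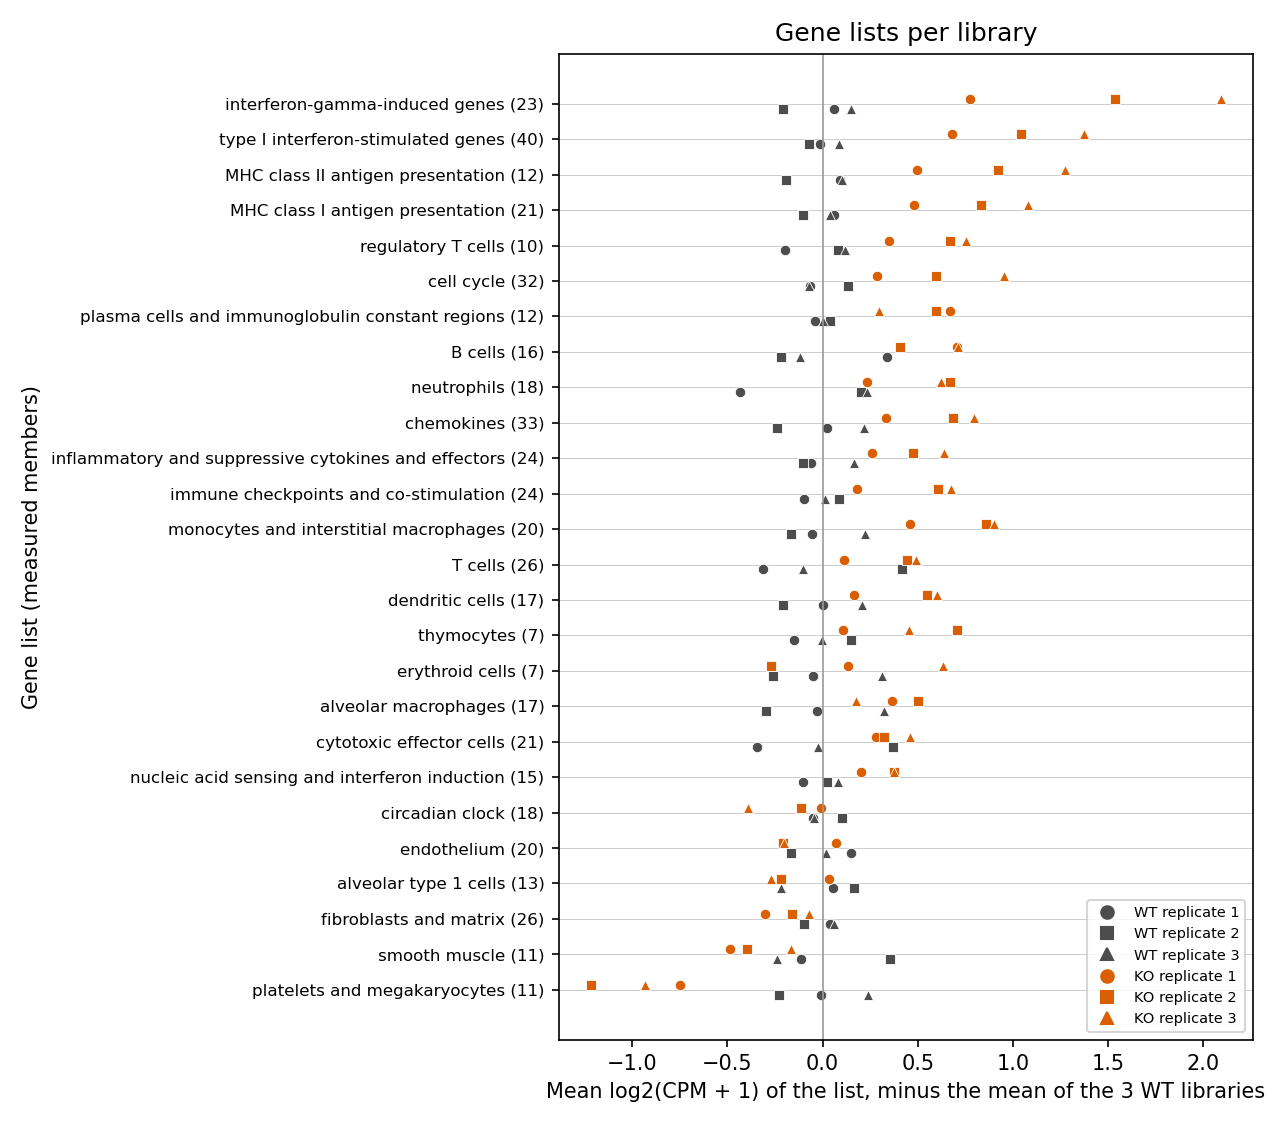
Mean log2(CPM + 1) of each called list and of the erythroid list in each library, as the difference from the mean of the 3 WT libraries; points are single libraries, WT in grey and KO in orange. The 3 KO libraries lie at 0.68, 1.04 and 1.38 for type I interferon-stimulated genes and at −0.75, −1.22 and −0.93 for platelet genes, while the groups overlap for fibroblasts, neutrophils, smooth muscle, dendritic cells, T cells, cytotoxic cells, alveolar macrophages, endothelium, alveolar type 1 cells, the circadian clock, thymocytes and erythroid cells.

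The other lists were not called by camera. Of these, the club and ciliated cell list held 1 gene that rose, Cyp2f2, a cytochrome P450 of club cells (85.3 ± 21.9 to 199.2 ± 63.9 CPM, edgeR adjusted p = 0.044), with 3 higher and 2 lower adjusted over the list alone and a median of 0.05. The immature neutrophil granule list held 1 of 5, Lcn2 (log2 fold change 1.06 ± 0.19, adjusted p = 0.0161), both over all genes and adjusted over the list alone, with a median of 0.17. With 1 library left out in turn (WT replicates 1, 2 and 3, then KO replicates 1, 2 and 3), 0, 0, 3, 3, 0 and 0 airway genes and 0, 0, 1, 1, 0 and 0 granule genes rose. Cyp2f2 and Lcn2 thus did not pass in 4 of the 6 fits. The airway median was between −0.03 and 0.20 and the granule median between −0.50 and 0.24. No member passed, over all genes or adjusted over the list alone, in the lists of the mitochondrial genome (median 0.18), replication-dependent histones (−0.15), erythroid cells (0.34), hypoxia and glycolysis (0.11), mesothelium (0.10), mast cells, basophils and eosinophils (0.03), basal keratins and mammary epithelium (0.02), cardiac muscle (0.00), immediate early and heat shock genes (0.00), skeletal muscle (0.30), adipocytes (0.10) and alveolar type 2 cells (−0.01). The median and the direction of camera or the mean differed in sign in the mesothelium, mast cell, keratin, cardiac, immediate early, adipocyte and alveolar type 2 lists. Camera p-values of these 12 lists lay between 0.0872 (mitochondrial genome) and 0.951 (alveolar type 2) after adjustment.

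KO replicate 1 stood between the groups on the first principal component, at 0.2, with WT libraries at −31.1 to −21.0 and the other KO libraries at 34.9 and 46.7, and it had the lowest interferon values of the KO libraries. Without it 404 genes were higher and 174 lower, and 31 of the 40 interferon-stimulated genes rose. Without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3, the higher genes numbered 28, 22, 23 and 36, the lower genes 5, 2, 2 and 4, and the interferon-stimulated genes that rose 6, 6, 8 and 10, whereas without WT replicate 3 there were 188, 34 and 18. No fixed list was called with an estimated correlation (11 of 41 had an unadjusted p under 0.05) or by directional fry. Fry's mixed test, which asks for change in either direction, called 17, and an offset for gene length and GC chosen after seeing the data left 103 higher and 21 lower genes. Across genes, which are not independent replicates, the Spearman correlation of log2 fold change with exonic length was −0.279.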

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

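The length and GC offset was chosen after seeing the data, and the other alternatives before. Of 51 genes named in this text that passed the test, which include Gm15056 from outside the rule, 11 passed in all 16 other fits at the same threshold, not counting the minimum fold. These were Bst2, Stat2, Ifi44, Tap2, Psmb9, H2-T23, Ly6c2, Ccl2, Igkc, Ighm and Ppbp. No called gene changed direction. DESeq2's size factors, upper-quartile scaling, library size alone, the filter at 1 CPM, limma-voom and robust=FALSE kept the counts of higher and lower genes within 1.5 times. Without a filter 578 genes were higher and 225 lower, with DESeq2 354 and 233, 315 and 160 at an adjusted p under 0.1, 23 and 2 at 0.01, 1 and 1 with a minimum fold of 1.5, and with the length and GC offset 103 and 21. Leaving out 1 replicate gave 22 to 404 higher and 2 to 174 lower genes, and fewer samples were then tested. Without WT replicate 1, 2 or 3 or KO replicate 1, 2 or 3, 31, 23, 138, 216, 24 and 40 of the 221 calls were kept. Same-numbered libraries deviated together with correlations of 0.027, −0.019 and 0.009, and not every library correlated best with its own number; with the replicate number as a replicate block, 309 genes were higher and 96 lower. Cd274 and Cxcl9 passed without a filter (log2 differences 1.64 and 3.33, edgeR adjusted p = 1.05e-33 and 1.15e-79). The main fit had nearly the same differences (1.645 and 3.334) at edgeR adjusted p of 0.161 and 0.133. The very small unfiltered p-values thus came from the changed variance fit, and are not read as stronger evidence. Both genes also passed with DESeq2 (1.635 and 3.315, adjusted p = 0.0113 and 0.00107) and with robust=FALSE (1.645 and 3.334, adjusted p = 0.0149 and 0.00671). They did not pass with the other scalings, limma-voom (adjusted p = 0.245 and 0.305) or the block. Cd8a passed without a filter (0.95, adjusted p = 0.0223) and with DESeq2 (0.94, adjusted p = 0.0419). Cxcl10 did not pass with limma-voom (2.49, adjusted p = 0.201). Its adjusted p ranged from 4.67e-37 without a filter, where the same caution applies, to 0.201. When 1 replicate was left out, log2 differences were 1.21 to 1.97 for Cd274, 2.64 to 3.88 for Cxcl9, 2.20 to 2.96 for Cxcl10 and −0.0536 to 0.0898 for Ifnar1, which was below 0 without WT replicate 3 (−0.0536) and KO replicate 2 (−0.02). Those of Gzmb ran from 0.22 without WT replicate 1 to 0.73 without WT replicate 2, and with the offset Gzmb was at 0.28. For the other 87 genes, counting those chosen after their values were seen, limma-voom ended 14 calls and added 2, DESeq2 added 18, and the offset ended 16. Of the fixed lists, 0 were higher and 0 lower with an estimated correlation or with fry, at unchanged medians for the interferon (1.14), cytotoxic (0.23) and chemokine (0.49) lists, whose adjusted p were 0.114, 0.548 and 0.186 with an estimated correlation and 0.0778, 0.344 and 0.107 with fry. At a threshold of 0.01, 3 lists were lower. Leaving out 1 replicate gave 17 to 21 higher and 3 to 6 lower lists and a cytotoxic median of 0.0813 to 0.554. The endothelial call was lost without WT replicate 1, KO replicate 2 or KO replicate 3, the alveolar type 1 call without WT replicate 1 or 2 or KO replicate 2 or 3, the alveolar macrophage call without WT replicate 2 or KO replicate 2, the thymocyte call without WT replicate 1 or 3 or KO replicate 2, and the circadian call without WT replicate 2 or KO replicate 3, where its median was 0.05. NK cells were gained without WT replicate 2, and the airway and mitochondrial lists without WT replicate 3 or KO replicate 1. Camera on voom values ended the thymocyte call (adjusted p = 0.095), but 19 lists were still higher, so another list was gained. With the offset the cytotoxic (median 0.0952, adjusted p = 0.109) and alveolar macrophage lists (0.11, adjusted p = 0.184) were not called. Where not stated, the cause was not tested. At this depth, 0 counts for Ifnb1 do not tell a low level from none.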

Other observations

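Immunoglobulin variable segments were examined as a family defined by symbol after the data were seen. Of 66 measured segments, 63 had positive log2 differences, 2 rose over all genes and 4 adjusted over the list alone, with a median of 0.90 (limma camera adjusted p = 3.01e-10, and adjusted p = 0.113 with an estimated correlation when adjusted over all 46 fixed and added lists, or 0.0124 over the 5 added lists alone). Their median was 0.45 with the length and GC offset, and segments are short genes whose reads can be shared. Cytosolic ribosomal protein genes (80 measured, median 0.34) and respiratory chain genes (74 measured, median 0.32) had positive log2 differences in 78 and 68 members, with camera adjusted p of 1.34e-21 and 3.89e-17 (adjusted p = 0.286 and 0.164 with an estimated correlation, over all 46 lists). With the offset these medians were 0.21 and 0.18. T cell receptor variable segments (14 measured, median 0.35) did not pass, at an adjusted p of 0.0607, and had a median of −0.07 with the offset.

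Scgb1a1, the club cell secretory protein gene, was chosen after its values were seen: it had 502.4 ± 260.5 CPM in WT and 2090 ± 925.1 CPM in KO lungs (log2 difference 2.06 ± 0.50, edgeR adjusted p = 0.158). Gm15056, outside the rule for named genes and also chosen after its values were seen, had 0 counts in the 3 WT libraries and 25, 118 and 170 in the KO libraries, at least 104-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00482). Among genes with low counts, KO replicate 1 had 49.9% zeros and a variance of 4.37 times the mean, against 61.3 to 71.4% and 5.98 to 9.51 in the other libraries.

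The tests of blood content and of the length trend among the higher genes were chosen after the results were seen, and the other tests below before their results were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 170 higher genes, and the highest other split gave 1 in its larger direction, so 1 of the 10 splits reached the real value. For the lower genes the values were 51 and 0, again reached by 1 split. For the lists they were 19 in the larger direction and 6 in the smaller, and the highest other splits gave 19 and 6 as well, so 2 of the 10 splits reached each. The split of WT replicates 1 and 2 with KO replicate 1 against the rest called 24 lists, close to the 25 of the real split, so the number of list calls alone does not set the KO lungs apart.

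Higher interferon-stimulated genes were weighed against a higher share of leukocytes and of monocytes in the KO lungs. The median of the interferon list lay 0.78 above that of 19 pan-leukocyte genes (0.37), a list added after the data had been seen. The gap was more than their interquartile range of 0.30, and the difference of the list means was higher in all 3 KO libraries than in all WT libraries. This argues against an even rise of all leukocytes as the whole cause but not as a part of it. It does not test a rise of single kinds of leukocyte. Of the 19 genes, 6 rose over all genes and 12 adjusted over the list alone, and all 19 had positive log2 differences (camera adjusted p = 4.99e-13, and adjusted p = 0.21 with an estimated correlation, over all 46 lists); the most abundant, Lcp1 and Laptm5, had 0.35 ± 0.14 and 0.26 ± 0.14, and 1 of the 19 is also in another list. Against the monocyte list (median 0.46) the gap was 0.68, within that list's interquartile range of 1.39, while the difference of the list means was higher in all KO libraries (0.23, 0.18 and 0.48) than in all WT libraries (0.04, 0.10 and −0.14), so the 2 measures point different ways and a rise in monocytes is not excluded. The most abundant of its 20 members, Ace (1603 ± 110.4 CPM in WT) and Fn1 (1287 ± 163.0 CPM), are expressed by other lung cells too and had log2 differences of −0.18 ± 0.12 and −0.35 ± 0.12.

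Lower platelet genes were weighed against less blood left after perfusion and against the length trend. The platelet median lay 1.35 below the erythroid median of 0.34 (−1.35), which itself was 0.28, 0.20, 0.55, 0.42, 0.57 and −0.05 without WT replicates 1, 2 and 3 and KO replicates 1, 2 and 3, and the difference of the list means was lower in all 3 KO libraries than in all WT libraries. Hbb-bs and Hba-a1 were at 98.2 ± 10.7 and 66.6 ± 6.70 CPM in WT and at 138.3 ± 52.9 and 69.7 ± 28.2 CPM in KO lungs. Relative to the WT mean, the erythroid list means overlapped, at −0.052, −0.26 and 0.313 in WT and 0.131, −0.271 and 0.631 in KO libraries. A platelet fall without a like erythroid fall argues against less whole blood as its whole cause. Less blood in single lungs, such as KO replicate 2, is not excluded. None of the 7 erythroid genes is in another list, and 2 of the 11 platelet genes are. With the length and GC offset the platelet median was −1.18, so the length trend does not account for it. The most abundant platelet gene, Itgb3, which other lung cells express too, had 61.1 ± 3.68 CPM in WT and 57.2 ± 7.28 CPM in KO lungs (log2 difference −0.09 ± 0.13, edgeR adjusted p = 0.798), and the cause was not tested further.

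The link of fold change to gene length was weighed as a technical trend between libraries. Exonic length had a median of 2824.5 bases among the higher genes, 8402 among the lower and 4234 among all tested genes. With the offset, 97 of the 170 higher genes stayed called and their median went from 1.02 (interquartile range 0.63) to 0.97 (0.63), which argues against the trend as their whole cause. Of the 51 lower genes 16 stayed called, and the median of all 51 went from −0.56 (0.12) to −0.46 (0.21). Among the other 35, which lost the call, the median log2 fold change went from −0.54 to −0.40 and the median SE from 0.114 to 0.108. How far the smaller fold changes or the adjustment over all genes ended these calls was not tested. For the lower genes a length trend between libraries and a difference between the groups cannot be told apart, since 35 of the 51 calls ended while the median kept most of its size.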
